A study of Mus musculus with 6 samples.

How the data were processed

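Gene expression was measured by sequencing of polyadenylated RNA from mouse cells. E14 is a mouse embryonic stem cell line, here carrying a transgene in which regulatory sequence of Nkx2-5, a transcription factor gene of early heart cells, drives a green fluorescent protein. Per the labels' protocols, the stem cells were kept on mouse embryonic fibroblast feeders with leukemia inhibitory factor, differentiated as embryoid bodies in hanging drops without that factor, dissociated on day 6, and sorted for the fluorescent reporter. The 6 libraries form 2 groups, 3 control libraries and 3 libraries from cells in which Lmna, the gene of lamin A and lamin C, was knocked out. Nothing in the labels says that the replicates came from separate cultures or clones, so the p-values measure the spread between these samples, which may be technical.

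The authors deposited raw counts as whole numbers per RefSeq transcript, per the file headers. The submitters' processing notes name STAR, DESeq2, edgeR and the mouse build mm10, without versions; the counting program, its strand setting and its annotation release are not given in the sources used here. The headings of the value columns begin with ES, while the sample titles and the name of the table give cardiac progenitor cells. The columns were mapped by group and replicate number, and the headings leave unsettled which cells the table holds. In the control libraries Hand1, a transcription factor gene of heart mesoderm, was at 677 ± 105 CPM, and Zfp42, a marker of naive stem cells, was at 1.86 ± 0.21 CPM (SD, n = 3 each). Hand1 is also on the trophoblast list used below, and Nkx2-5 was at 18.4 ± 1.93 CPM in the same libraries. The table has 29239 transcript rows for 14928 gene symbols. The smallest row total over the 6 libraries was 21 counts, so genes below that level are missing from the table. Of the symbols, 6583 had more than 1 transcript row, and 2658 rows had the same 6 counts as another row. To avoid using reads more than once, 1 row per gene was used, that with the highest total count. Genes with close copies elsewhere in the genome are uncertain: Gapdh, a gene with many pseudogenes, had only 6.65 ± 0.834 CPM (counts per 1e+06 counts of the scaled library; SD, n = 3) in the control. Overlapping and antisense genes are uncertain too, since the strand setting is not known.

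The same table holds other values that the authors computed. These are a normalized signal headed TMM, which per the file headers and the values is each raw count divided by 1 factor per library, and which lies within 0.016% of a median-of-ratios factor. They also include RPKM values per the file headers, a transcript length column, and the authors' DESeq2 results, with a log2 fold change and its standard error, a Wald score, and a p-value with its adjusted p-value for each transcript row. None of these entered the tests. The deposited fold changes are positive where the knockout is higher.

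The counts were tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM normalization), with group as the only term. Genes were kept by filterByExpr with its default settings (smallest count 10, smallest total 15), which left 13526 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Counting intervals given for genes with few counts cover counting error only. Values are TMM-scaled CPM with the mean and SD over 3 libraries, and log2 fold changes are knockout over control with their standard errors. Before the data were examined, 34 gene lists were fixed, covering heart cells, other lineages an embryoid body or the sort could hold, pluripotency, the nuclear envelope, signalling, proliferation, metabolism and stress. The 31 lists with at least 5 tested members were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes.

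The genes named were set by a rule fixed at the same time. Lmna and Nkx2-5 are always named. The 10 largest rises and the 10 largest falls follow, among called genes with groups that do not overlap and a mean of at least 5 CPM, leaving out Lmna and symbols that are provisional or clone names. For each list described, up to 2 called members that rose and 2 that fell with the smallest adjusted p are named, or the 2 with the highest mean where none was called. Any other gene named was chosen after its values were seen. Of the gene symbols, 14895 matched the RefSeq table of GRCm38 by accession and 23 by name, and coordinates are those of GRCm38, the assembly of mm10.

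Other settings were size factors by median of ratios, upper quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, and a test for changes above 1.5-fold (glmTreat). Further settings were chosen after seeing the data, namely other ways to choose the transcript row, scaling by library totals, and thinning to equal depth. The steps were tested on simulated counts for the 13526 genes, with the means, library sizes and dispersions of these libraries and 10 simulations of 200 changed genes. For knockout against control, edgeR recovered 73.6% of genes changed 1.5-fold, 90.3% of those changed 2-fold and 99.8% of those changed 4-fold. Of its calls, 7.98% were unchanged genes, above the nominal 5%, against 5.04% for DESeq2. These rates need not hold where more genes change, and edgeR called 3770 genes in the data. Camera at the preset correlation called 1.67% of unshifted lists when genes varied independently.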

Results

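The transcriptome of reporter-sorted cardiac progenitor cells was measured on day 6 of embryoid body differentiation in 3 control and 3 Lmna knockout libraries. The total count over 1 transcript row per gene was 7274548, 8966246 and 8843326 in control replicates 1 to 3, and 10943912, 9815122 and 9583119 in knockout replicates 1 to 3. All 6 libraries were distinct, since replicate pairs differed beyond sampling noise, with a chi-square per gene between 1.68 and 6.42. The value columns of the table are headed as embryonic stem cells, and were taken as the progenitor libraries by the sample titles and the name of the table. The comparison asks how the loss of lamin A and C changes gene expression in cells sorted as cardiac progenitors. The labels do not say which clones the libraries came from. A difference between cell clones therefore cannot be told from an effect of lamin loss in any of the results.

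Lmna (transcript NM_001002011; chromosome 3, 88481148 to 88509932, GRCm38) fell from 101 ± 2.99 CPM in the control to 2.97 ± 0.308 CPM in the knockout (SD, n = 3 each), a log2 fold change of -5.09 ± 0.103 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.6e-12). It had 701, 898 and 896 counts in the control libraries and 29, 32 and 30 in the knockout libraries, so each library matched its label. Nkx2-5, the gene behind the reporter (chromosome 17, 26838664 to 26844988), rose 3.33-fold, from 18.4 ± 1.93 to 61.5 ± 13.6 CPM (adjusted p = 2.1e-06). The cells were sorted on this reporter, so the level of Nkx2-5 may also reflect the sort. Of 13526 genes tested, edgeR called 3770, with 1872 higher and 1898 lower in the knockout. Among these, 598 were at least 2-fold higher and 329 at least 2-fold lower. A test for changes above 1.5-fold called 796 genes, 497 higher and 299 lower. The authors' deposited table lists 6031 transcript rows at an adjusted p under 0.05, from 3170 genes. With scaling by library totals the share of higher calls was 60.4% in place of 49.7%.

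**Figure D1:**
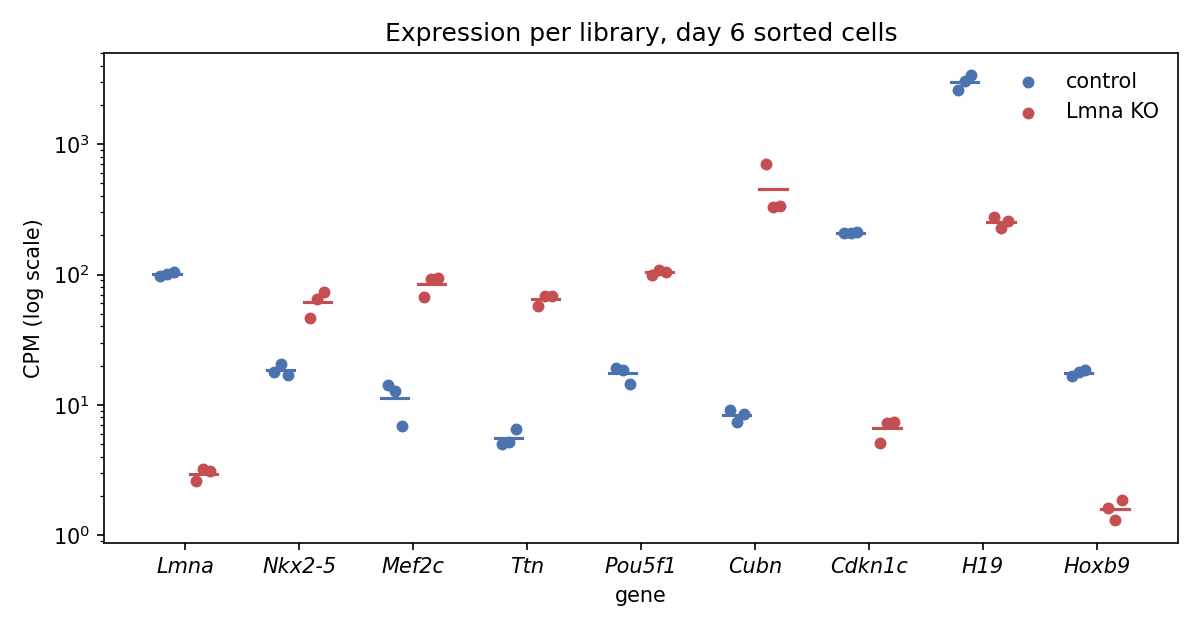
Scaled expression in CPM (log axis) of 9 named genes in the 3 control (blue) and 3 Lmna knockout (red) libraries, with horizontal lines at the group means. Lmna fell from 101 to 2.97 CPM and Nkx2-5 rose from 18.4 to 61.5 CPM.

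Among genes with a mean of at least 5 CPM, the largest rise was that of Srgn, which encodes the proteoglycan serglycin, from 0.432 ± 0.351 to 101 ± 23.7 CPM (log2 fold change 7.91 ± 0.297 SE, and 8.70 without control replicate 1). Spock1, which encodes another proteoglycan, followed at 6.97 ± 0.404. Cubn and Amn, which encode the 2 subunits of the cubilin and amnionless endocytic receptor, rose by 5.77 ± 0.309 and 5.03 ± 0.344 on the log2 scale. Pax1 rose by 5.49 ± 0.319, Vgll2 by 5.43 ± 0.235 and Foxi3 by 4.08 ± 0.276, all genes of transcriptional regulators. The water channel gene Aqp8 rose by 5.01 ± 0.311, and the apolipoprotein genes Apoa4 and Apoa1 by 4.77 ± 0.418 and 4.04 ± 0.332. Apoa1 stood at 4.72 without control replicate 3. Each was higher in 3 of 3 knockout libraries, with adjusted p between 8.92e-10 (Srgn) and 2.13e-06 (Apoa4) by edgeR. Among the knockout libraries, replicate 1 was highest for Srgn, Spock1, Cubn, Amn, Aqp8, Apoa4 and Apoa1. Cubn was at 701 CPM there, against 329 and 338 CPM in replicates 2 and 3. Pax1 and Vgll2 were lowest in replicate 1, with Pax1 at 30.3 CPM against 49.1 and 48.2 CPM, and Foxi3 lay between.

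Among genes with a mean of at least 5 CPM, the largest fall after Lmna was that of Cdkn1c, an imprinted gene for an inhibitor of the cell cycle, from 210 ± 0.641 to 6.59 ± 1.33 CPM, a 32-fold fall (adjusted p = 1.6e-12 by edgeR). The other genes of the 10 largest falls were the imprinted genes Mest and H19, the microRNA gene Mir675, and 6 Hox genes, described below with their groups. Mir675 had a log2 fold change of -3.76, but it lies inside H19 (chromosome 7, 142577064 to 142577147, within 142575530 to 142578146), so its counts cannot be told from those of H19.

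Genes of heart cells were higher on balance in the knockout in the cardiac transcription factor and sarcomere lists. The cardiac hormone and fetal program list, described below, was not called. Of 28 tested cardiac transcription factor genes, 17 rose and 2 fell (17 and 3 adjusted over the list alone), with a median log2 fold change of 0.57 (camera, adjusted p = 1.02e-08, and adjusted p = 0.102 with an estimated correlation). Mef2c, which drives heart muscle genes, rose from 11.3 ± 3.92 to 84.7 ± 15.2 CPM, and Smarcd3, which encodes a chromatin remodelling subunit of heart development, rose 2.36-fold. Tbx3 and Pitx2 fell 1.44-fold and 1.52-fold. Of 25 sarcomere genes, 15 rose and 4 fell (15 and 4 adjusted over the list alone), with a median of 1.05 (camera, adjusted p = 6.97e-11, and adjusted p = 0.205 with an estimated correlation). Ttn, the gene of the giant protein titin, rose 11.5-fold from 5.57 ± 0.8 to 64.7 ± 6.28 CPM, and Nebl rose 4.16-fold, while the tropomyosin genes Tpm1 and Tpm2 fell 1.37-fold and 1.41-fold. The sarcomere median against the control mean was 0.57 in knockout replicate 1, and 1.13 and 1.12 in knockout replicates 2 and 3. Without knockout replicate 1 the counts were 16 higher and 4 lower for sarcomere genes and 16 and 2 for the cardiac transcription factors.

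Genes of calcium handling and ion channels and of the second heart field also rose on balance. Of 22 calcium and channel genes, 12 rose and 2 fell (the same numbers adjusted over the list alone; median 0.62; camera, adjusted p = 0.000405, and adjusted p = 0.205 with an estimated correlation). The potassium channel gene Kcnj3 rose 5.59-fold and the sodium-calcium exchanger gene Slc8a1 rose 3.5-fold, while the calcium channel genes Cacna1g and Cacna1c fell 1.83-fold and 1.63-fold. Of 22 second heart field genes, 11 rose and 3 fell (11 and 5 adjusted over the list alone; median 0.31; camera, adjusted p = 0.000537, and adjusted p = 0.205 with an estimated correlation). Six1 rose 9.78-fold from 4.95 ± 0.723 to 48.2 ± 7.36 CPM, whereas the Wnt ligand gene Wnt5a and the retinoic acid synthesis gene Aldh1a2 fell 2.01-fold and 2.45-fold.

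**Figure D2:**
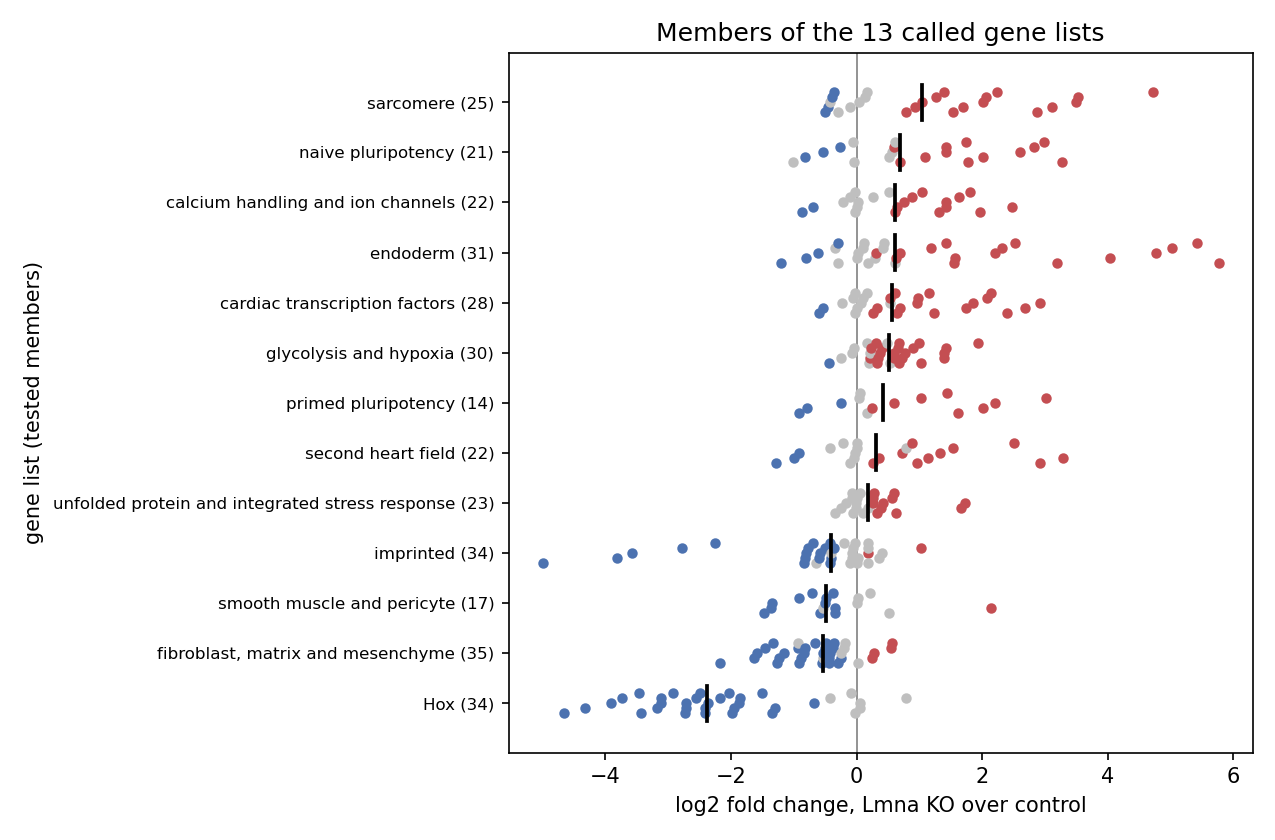
Log2 fold change (knockout over control) of each tested member of the 13 called lists, with members called higher in red, called lower in blue and not called in grey, and the list median as a black bar. The medians run from -2.39 for the Hox genes to 1.05 for the sarcomere genes, and most lists hold members that moved in both directions.

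Pluripotency genes were higher in the sorted knockout cells. Of 21 naive pluripotency genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone; median 0.69; camera, adjusted p = 1.54e-12, and adjusted p = 0.0912 with an estimated correlation). Pou5f1, which encodes the core pluripotency factor OCT4, rose 6.05-fold from 17.4 ± 2.55 to 105 ± 4.4 CPM, and Utf1 rose 7.87-fold from 5.96 ± 1.63 to 46.2 ± 2.24 CPM. Tbx3 and Sall4, which are also expressed outside pluripotent cells, fell 1.44-fold and 1.2-fold. Zfp42, a marker of naive stem cells that was chosen after its values were seen, was at 1.86 CPM in the control and 2.7 ± 1.14 CPM in the knockout (adjusted p = 0.257 by edgeR). Of 14 primed pluripotency genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.42; camera, adjusted p = 0.000117, and adjusted p = 0.205 with an estimated correlation). Otx2 rose 3.08-fold and Zic2 rose 2.71-fold, while Lef1 and Krt18 fell 1.87-fold and 1.19-fold.

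Endoderm genes moved unevenly. Of 31 tested, 16 rose and 4 fell (19 and 4 adjusted over the list alone; median 0.61; camera, adjusted p = 1.78e-09, and adjusted p = 0.244 with an estimated correlation). Cubn rose from 8.36 ± 0.831 to 456 ± 212 CPM and Amn from 0.866 ± 0.49 to 29.4 ± 9.98 CPM, both expressed in the visceral endoderm of the embryo. Foxa1 and Shh, which are expressed in definitive endoderm among other tissues, fell 2.32-fold and 1.74-fold. Knockout replicate 1 stood apart in this list, with a median of 0.88 against the control mean compared with 0.47 and 0.46 in replicates 2 and 3. Without that library 15 members were called higher and 4 lower. The count of falls was 2 without control replicate 2, knockout replicate 2 or knockout replicate 3.

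Genes of connective tissue and smooth muscle were lower. Of 35 fibroblast, matrix and mesenchyme genes, 25 fell and 4 rose (29 and 4 adjusted over the list alone; median -0.54; camera, adjusted p = 7.1e-12, and adjusted p = 0.115 with an estimated correlation). Prrx1, a transcription factor gene of mesenchyme, fell 4.5-fold from 25.6 ± 4.71 to 5.7 ± 0.425 CPM, and Thbs1, the gene of the matrix protein thrombospondin, fell 3-fold from 236 ± 53.2 to 78.8 ± 2.88 CPM. Pdgfra and Sparc each rose 1.47-fold. The count of rises was 2 without control replicate 1 or knockout replicate 1. Of 17 smooth muscle and pericyte genes, 11 fell and 1 rose (12 and 2 adjusted over the list alone; median -0.48; camera, adjusted p = 0.000678, and adjusted p = 0.355 with an estimated correlation). The smooth muscle actin gene Acta2 fell 1.88-fold from 1010 ± 188 to 539 ± 10.8 CPM and Pdgfrb fell 1.63-fold. The exception was Myocd, which is also on the cardiac list and rose 4.4-fold. Without control replicate 3, 2 members were called higher.

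Hox genes, which set position along the body axis, showed the largest fall of any list. Of 34 tested, 28 fell and none rose (29 adjusted over the list alone; median -2.39; camera, adjusted p = 2.44e-35, and adjusted p = 0.0912 with an estimated correlation). Without control replicate 1 or knockout replicate 2, 1 member was called higher. Falls were seen in all 4 clusters, with 8 of 9 genes lower in the cluster on chromosome 6, 5 of 9 on chromosome 11, 7 of 8 on chromosome 15 and 8 of 8 on chromosome 2. By paralogue number, 5 of 10 genes of groups 1 to 4 fell (median -0.86), compared with 11 of 11 of groups 5 to 8 (median -2.17) and 12 of 13 of groups 9 to 13 (median -3.11). The uncalled genes of groups 1 to 4 were Hoxa1 and, on chromosome 11, Hoxb1, Hoxb2, Hoxb3 and Hoxb4. The others, Hoxa3, Hoxc4, Hoxd1, Hoxd3 and Hoxd4, had log2 fold changes of -2.92, -1.51, -1.3, -2.72 and -2.42. The smaller fall of groups 1 to 4 thus lay largely in the chromosome 11 cluster. Among the strongest, Hoxa9 fell 20-fold from 20.3 ± 6.78 to 1.02 ± 0.458 CPM and Hoxd10 fell 15.1-fold. Hoxb9 fell 11-fold and Hoxd9 fell 5.13-fold. Hoxa11, Hoxd11 and Hoxa10 had log2 fold changes of -3.44 ± 0.385, -3.11 ± 0.274 and -3.11 ± 0.288 (SE). Hoxa6 had 3 counts in the knockout and 69 in the control, a ratio of 0.0348 with a 95% counting interval of 0.00701 to 0.106, and the list median is the same with this gene at the upper end of that interval.

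**Figure D3:**
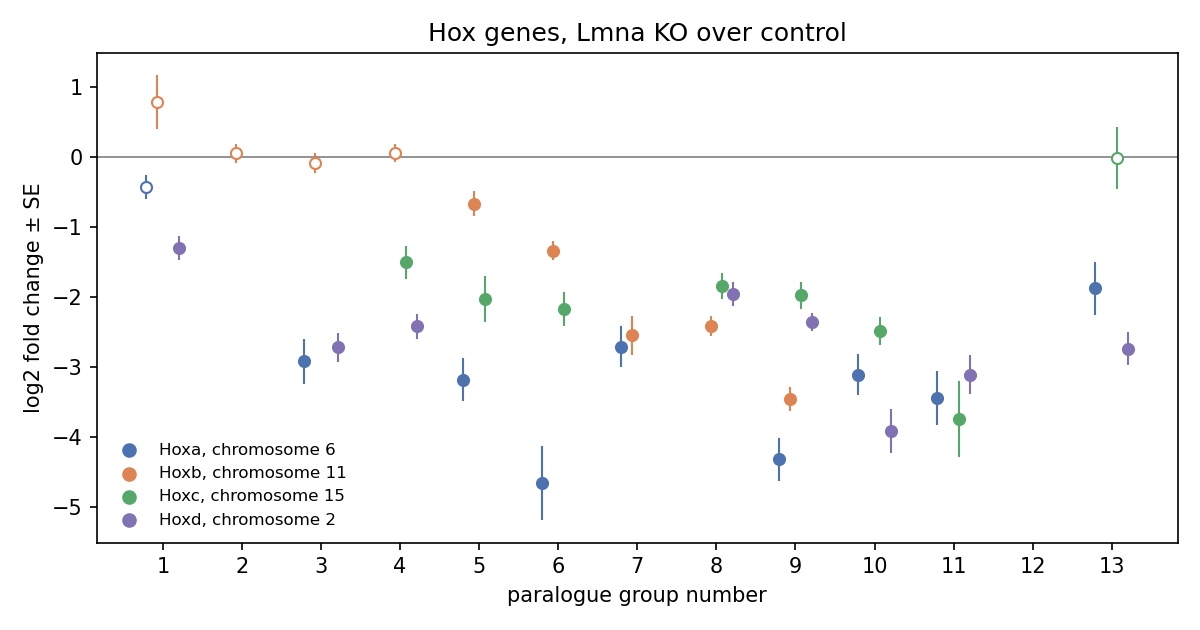
Log2 fold change ± SE (knockout over control) of the 34 tested Hox genes by paralogue group number, coloured by cluster, with filled points for called genes and open points for the others. The members of the chromosome 11 cluster numbered 1 to 4 lie close to or above 0, while its member Hoxb9 is at -3.46.

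Imprinted genes, expressed from 1 parental copy, fell on balance. Of 34 tested, 17 fell and 2 rose (18 and 5 adjusted over the list alone; median -0.41; camera, adjusted p = 2.03e-17, and adjusted p = 0.102 with an estimated correlation). The size of the falls was uneven. Cdkn1c fell 32-fold (chromosome 7, 143458339 to 143461059). Mest (chromosome 6, 30733506 to 30748466) fell 14-fold from 1770 ± 109 to 126 ± 24.1 CPM, and H19 fell 11.9-fold from 3010 ± 396 to 254 ± 25.1 CPM. Igf2, which lies next to H19 and was chosen after its values were seen, was at 11500 ± 163 and 11300 ± 387 CPM, a log2 fold change of -0.02 ± 0.05 SE (adjusted p = 0.8 by edgeR). Copg2, which overlaps the end of Mest and was likewise chosen afterwards, fell 5.53-fold, and its reads may partly be those of Mest. Grb10 and Xist were the 2 members called higher, at log2 fold changes of 0.18 and 1.03. Neither call held in all settings, and each was lost without any 1 of control replicates 1 and 2 and knockout replicates 1 to 3, with adjusted p up to 0.129 and 0.11. No imprinted gene was called higher without control replicate 2 or any 1 knockout replicate.

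**Figure D4:**
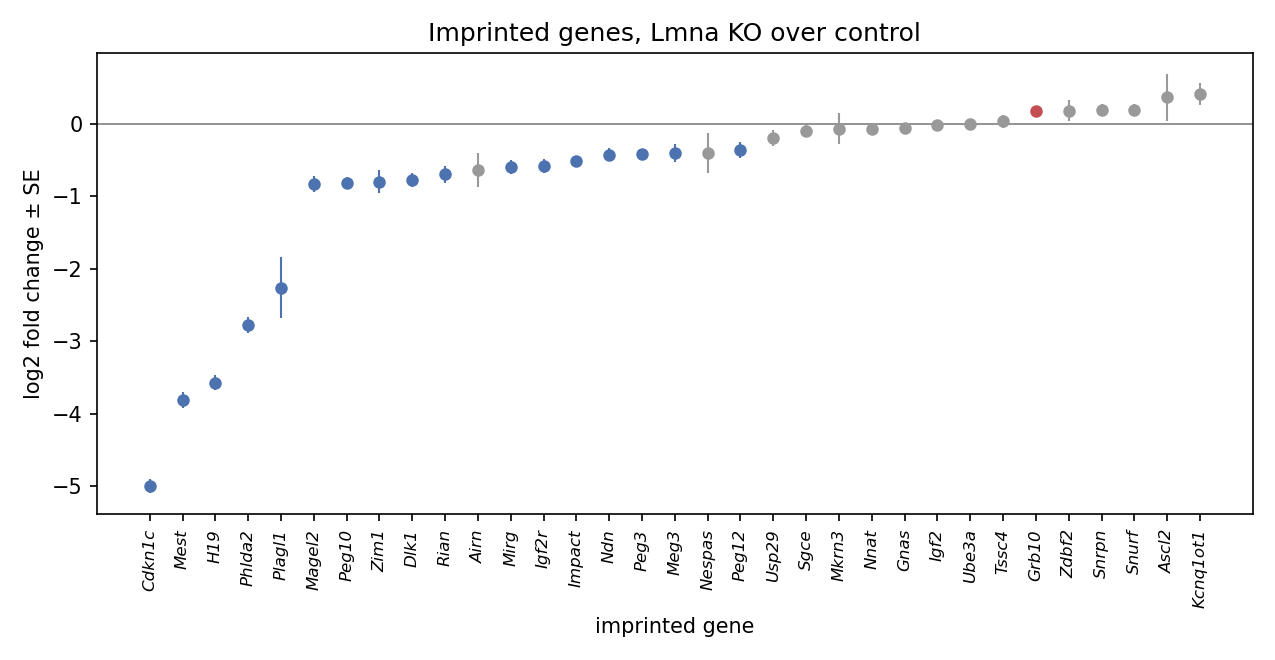
Log2 fold change ± SE (knockout over control) of the tested imprinted genes other than Xist, with genes called lower in blue, called higher in red and not called in grey. Cdkn1c, Mest at -3.81 and H19 at -3.57 stand below the other genes, and Igf2 lies at -0.02.

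Y-linked genes differed between the groups and within the knockout. The 4 tested genes were too few for a list test, and 3 of them were called lower. Kdm5d (chromosome Y, 897566 to 943813) had 41 counts in the control and 1 in the knockout, a ratio of 0.0195 with a 95% counting interval of 0.000483 to 0.115. Ddx3y fell 2.08-fold, a call that DESeq2 did not make (adjusted p = 0.163). It stood at 6.86 CPM in knockout replicate 1 but at 24.3 and 22.1 CPM in knockout replicates 2 and 3, compared with 31 to 41.9 CPM in the control.

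Genes of glycolysis and the hypoxia response rose together. Of 30 tested, 21 rose and 1 fell (24 and 1 adjusted over the list alone; median 0.51; camera, adjusted p = 1.26e-10, and adjusted p = 0.119 with an estimated correlation). Pdk1, which restrains the entry of pyruvate into mitochondria, rose 2.64-fold, and the lactate transporter gene Slc16a3 rose 2.67-fold from 96.3 ± 19.6 to 256 ± 20.8 CPM. The glucose transporter gene Slc2a3 fell 1.36-fold. Of 23 genes of the unfolded protein and integrated stress responses, 11 rose and none fell (11 and 2 adjusted over the list alone; median 0.18; camera, adjusted p = 0.0118, and adjusted p = 0.16 with an estimated correlation). Atf4, the main transcription factor of the integrated stress response, rose 1.55-fold, and its target Trib3 rose 3.16-fold. Without control replicate 1 or knockout replicate 1, 1 member of this list was called lower. Of 42 nuclear genes of oxidative phosphorylation, none rose and 5 fell (0 and 3 adjusted over the list alone; median -0.02; camera, adjusted p = 0.594), with Ndufa9 1.28-fold and Ndufv1 1.18-fold lower. The call for Ndufv1 was lost without control replicate 2 (adjusted p = 0.0623). The oxidative phosphorylation counts were 1 higher and 3 lower without control replicate 1, and 1 and 2 without knockout replicate 1. They were 0 and 2 without control replicate 2 or knockout replicate 3.

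Other signalling and proliferation lists held changes in both directions and were not called by camera. Their counts were the same adjusted over the list alone, except 8 higher and 10 lower for BMP and TGF-beta and 7 and 5 for Notch. Of 28 Wnt targets and ligands, 7 rose and 12 fell (median log2 fold change -0.15, adjusted p = 0.203), with Lgr5 2.9-fold and Lef1 1.87-fold lower and Sfrp5 8.23-fold and Fzd7 1.6-fold higher. Of 29 BMP and TGF-beta genes, 8 rose and 9 fell (median -0.12, adjusted p = 0.414), with Id4 2.46-fold and Bmp7 1.67-fold higher and Bambi 1.85-fold and Bmp2 1.51-fold lower. Of 18 Notch pathway genes, 6 rose and 5 fell (median 0.06, adjusted p = 0.866), with Jag2 2.18-fold and Hey2 1.53-fold higher and Notch2 1.43-fold and Notch3 1.27-fold lower. Of 39 cell cycle genes, 9 rose and 3 fell (median 0.1, adjusted p = 0.155), with Ccne1 1.38-fold and Kif11 1.24-fold higher and Ccne2 1.29-fold and Ccnd1 1.27-fold lower. The cell cycle list passed the threshold with limma-voom (adjusted p = 0.0156) and without control replicate 1 (adjusted p = 0.0237), and its adjusted p over all settings ranged from 0.0156 to 0.898. Of 22 other genes of the nuclear lamina and envelope, 3 rose and 1 fell (median 0.03, adjusted p = 0.715), with Syne2 1.54-fold and Nup210 1.41-fold higher and Sun2 1.19-fold lower. The Sun2 call was lost without control replicate 2 (adjusted p = 0.0506). Of 25 p53 targets, 3 rose and 5 fell (median -0.02, adjusted p = 0.785), with Gadd45a 1.38-fold higher and Plk2 1.68-fold lower. Several of these counts depended on single libraries. The BMP and TGF-beta rises numbered 4 without control replicate 2 and 5 without knockout replicate 1, and the Notch falls 3 without control replicate 2 or knockout replicate 2. The cell cycle rises numbered 4 without control replicate 2 or knockout replicate 3, and 5 without control replicate 3 or knockout replicate 2. The lamina and envelope falls numbered 3 without control replicate 1, 0 without control replicate 2 and 4 without knockout replicate 1. The p53 target falls numbered 3 without knockout replicate 3.

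Several lineage and response lists were likewise not called by camera. Their counts were the same adjusted over the list alone, except 10 higher and 4 lower for epithelial and 4 and 4 for trophoblast genes. Of 25 endothelial genes, 5 rose and 5 fell (median 0.01, adjusted p = 0.866), with Sox7 2.97-fold higher and Flt1 3-fold lower. Of 16 haematopoietic and erythroid genes, 2 rose and 2 fell (median 0.19, adjusted p = 0.905), with Coro1a 2.88-fold higher and Runx1 2.02-fold lower. Of 13 neural genes, 4 rose and 5 fell (median 0.01, adjusted p = 0.715), with Sox2 2.68-fold higher and Nefm 4.64-fold lower. Of 17 mesendoderm genes, 5 rose and 2 fell (median 0.13, adjusted p = 0.424), with the Brachyury gene T 2.06-fold higher and Cdx2 2.82-fold lower. Of 19 epithelial genes, 7 rose and 4 fell (median 0.18, adjusted p = 0.275), with Grhl2 2.86-fold higher and Krt19 1.78-fold lower. Of 6 epicardial genes, 1 rose and 2 fell (median -0.16, adjusted p = 0.181), and of 11 trophoblast genes, 3 rose and 3 fell (median 0.26, adjusted p = 0.401), with Krt7 1.74-fold higher and Peg10 1.77-fold lower. Of 6 tested cardiac hormone and fetal program genes, 1 rose and 1 fell (median 0.13, adjusted p = 0.818), with Fhl2 1.69-fold lower. Of 6 two-cell-like and germline genes, 2 rose and none fell (median 0.42, adjusted p = 0.475), with Rhox5 2.08-fold higher. Of 25 immediate early and heat shock genes, 3 rose and 5 fell (median -0.02, adjusted p = 0.905), with Fosb 1.97-fold higher and Hspb1 1.47-fold lower. Of 11 interferon response genes, 2 rose and 1 fell (median 0, adjusted p = 0.905), with Bst2 1.48-fold higher and Usp18 2.7-fold lower. Of 2 tested replication-dependent histone genes, Hist1h1c fell 1.67-fold, and no mitochondrially encoded gene has a row in the table.

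Counts in these uncalled lists also depended on single libraries. Endothelial genes numbered 2 higher and 3 lower without control replicate 2 or knockout replicate 2. They numbered 5 and 3 without control replicate 3, 3 and 4 without knockout replicate 1, and 4 and 3 without knockout replicate 3. Haematopoietic genes numbered 1 higher and 1 lower without control replicate 2, knockout replicate 2 or knockout replicate 3. They numbered 2 and 1 without control replicate 3, and 3 and 1 without knockout replicate 1. Neural rises numbered 7 without control replicate 3. Epicardial rises numbered 0 without control replicate 2, knockout replicate 2 or knockout replicate 3, and trophoblast rises 1 without control replicate 2 or knockout replicate 3. Cardiac hormone and fetal program rises numbered 0 without control replicate 1, control replicate 2, knockout replicate 1 or knockout replicate 3. Rises of two-cell-like and germline genes numbered 1 without knockout replicate 1. Falls of immediate early and heat shock genes numbered 3 without control replicate 2 or knockout replicate 2, and interferon response falls 2 without control replicate 1.

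In all, camera called 13 of 31 lists, 9 higher and 4 lower, and none with an estimated correlation, where the lowest adjusted p was 0.0912 and 7 lists were at an unadjusted p under 0.05, while fry called 17. At the preset correlation camera also called up to 13 lists when the 6 libraries were split into other groups of 3 that mix the genotypes. The median, mean and tested direction differed in sign for the cardiac hormone, endothelial, neural, immediate early, interferon and trophoblast lists, none of which camera called, while fry called the trophoblast list (adjusted p = 0.0426).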

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

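The count of called genes, 3770, ranged from 2967 with the replicate block to 3930 with no filter over the settings fixed before the data were examined, apart from glmTreat and single libraries left out. With 1 library left out it ranged from 2730 (without control replicate 2) to 3902 (without control replicate 1). The test for changes above 1.5-fold called 796 genes, 497 higher and 299 lower, because it asks for a larger change. In each of these settings the genes called both there and in the reported fit had the same direction. Lmna was called lower in each setting in which it was followed, which leaves out the test of all transcript rows (adjusted p = 2.79e-12 by glmTreat). Scaling by library totals, chosen after seeing the data, gave 3861 calls, of which 60.4% were higher, and upper quartile scaling gave 58.8% higher, with medians over all genes of 0.05 and 0.04. Replicate numbers did not pair the libraries, since the correlations of same-numbered deviations were -0.25, 0.03 and -0.22, and 1 of 6 libraries correlated best with its own number. The number of lists called was 13 or 14 in all settings except fry (17, with the epicardial, Wnt, BMP and TGF-beta, and trophoblast lists added) and camera with an estimated correlation (0). With the estimated correlation the 13 called lists lost their call, with adjusted p from 0.0912 to 0.355. Of 120 named genes other than Lmna, glmTreat called 65. In the other settings, all transcript rows left out, 109 kept their call, none changed direction, and 11 lost their call in at least 1 setting. These were Cd34, Itga2b, Sema3d, Xist, Ddx3y, Fabp3, Grb10, Sun2, Ndufv1, Eomes and Sycp3, with adjusted p up to 0.181. The settings for normalized values (pseudocounts, filters on low values) were not run, since the table holds counts. Depth limits what can be said of Kdm5d, Hoxa6 and the other genes with few counts, and genes under a total of 21 counts are missing from the table.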

Other observations

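The tests of X-linked genes and of gene surroundings were set before their results were seen, and the other tests in this part were chosen after. The test of gene surroundings was set on medians but run on means. Several of the largest rises were genes expressed in the pharyngeal region of the embryo, which lies next to the second heart field. A list of 23 such genes was written after Pax1, Foxi3, Six1 and Vgll2 had been seen among the rises, so it is not independent evidence. Of its 18 tested members, 13 rose and 1 fell, with a median log2 fold change of 2.03 (camera, p = 2.71e-21, and p = 0.0104 with an estimated correlation), and 6 of the tested members are also on other lists. Nkx2-3 rose from 1.44 ± 0.346 to 17.8 ± 3.34 CPM, Pax9 from 3.01 ± 1.82 to 19.7 ± 3.28 CPM and Foxg1 from 0.5 ± 0.182 to 6.25 ± 2.09 CPM (SD, n = 3 each), while Sox3 fell, with a log2 fold change of -0.79. Fgf3, Eya2, Ripply3 and Hand1 were not called, at log2 fold changes of -0.04, -0.04, 0.07 and 0.01.

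The first pattern is the rise of pluripotency genes. A smaller share of cardiac cells in the sort would by itself lower heart genes. The cardiac transcription factor list instead had a median log2 fold change of 0.57. Levels are means over all sorted cells, so a rise per cardiac cell could mask a smaller share. For the same reason, the rise of heart genes does not tell a change per cell from a larger share of cardiac cells. Undifferentiated stem cells carried through the sort remain possible, since 12 of 21 naive genes rose and no stem cell library gives the level that a given share would bring. Beside 105 CPM of Pou5f1, the highest knockout levels were 4.01 CPM for Zfp42, 6.38 for Esrrb, 1.3 for Dppa2, 0.823 for Nr0b1 and 5.25 for Dppa5a, which was called higher (mean 1.75 to 4.7 CPM, adjusted p = 0.000476 by edgeR). Control and knockout means were 1.86 and 2.7 CPM for Zfp42 and 3.19 and 4.89 CPM for Esrrb. They were 1.26 and 1.18 CPM for Dppa2 and 0.528 and 0.465 CPM for Nr0b1. Dppa2 and Nr0b1 thus did not rise, but levels this low do not decide the question. The reporter sort should remove stem cells, but its purity is not known here. Expression of the pluripotency genes in the progenitors themselves, or in other sorted cells, stays open.

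The second pattern is the fall of Hox and imprinted genes. Fewer fibroblast-like cells, feeder cells among them, would also lower matrix genes, and the fibroblast, matrix and mesenchyme list had a median log2 fold change of -0.54 (quartiles -0.94 and -0.28), less than the -2.39 of the Hox list (quartiles -3.06 and -1.38) but not less than the -0.41 of the imprinted list. This stays open, since the progenitors themselves may express matrix genes and so mask a larger loss. The reporter sort should remove feeder cells, though its purity is not known here. With the cell mixture unchanged, a switch of the maternal H19 and Igf2 region to the paternal state would raise Igf2 by about 1 on the log2 scale. The upper 95% limit of the Igf2 log2 fold change was 0.12, so a rise of that size was not seen. Parental copies were not told apart, so a change of cell mixture could mask such a rise. An effect of lamin loss and, untested, a difference in imprinting or differentiation state between cell clones are both open, because the labels do not say which clones the libraries came from.

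The third pattern concerns Y-linked genes. In knockout replicate 1, Ddx3y, Eif2s3y and Uty stood at 0.296, 0.292 and 0.311 of the mean of knockout replicates 2 and 3, with a pooled ratio of 0.296. Loss of the Y chromosome from part of the cells of that library stays open, since these are ratios of a single library and no DNA was measured. Cells with 2 active X chromosomes would raise X-linked genes, but their median log2 ratio was 0.049 (389 genes, 95% bootstrap interval 0.019 to 0.064). This ratio is knockout replicate 1 over the mean of knockout replicates 2 and 3, relative to autosomal genes. Its interval covers the spread between genes, not between libraries. Kdm5d, with 1 count over the 3 knockout libraries, is a separate matter. In knockout replicates 2 and 3 Eif2s3y was at least 1.05 times the control mean. Ddx3y and Uty were lower there than in the control but present, with Uty at 18 and 18.6 CPM against 24 to 30.9 CPM. Expression of these genes argues against loss of the whole chromosome in all knockout cells.

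Because lamins hold gene-poor chromatin at the nuclear edge, a further hypothesis was that genes in gene-poor surroundings rise without Lmna. The 598 genes called at least 2-fold higher had a mean of 15.9 protein-coding genes within 0.5 Mb, compared with 19 for uncalled genes in the same expression deciles (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The 301 genes called at least 2-fold lower, leaving out Hox genes, had a mean of 13.7, also against 19 (two-sided permutation p = 1e-05, again the smallest possible). The medians, which the preset rule named, were 11 in both sets, against 15 for uncalled genes in the same deciles. The medians were not tested. Gene-poor surroundings were thus seen for changes in both directions, so the result does not single out genes that rose, and neighbouring genes are not independent. Genes regulated in development may lie in such regions whatever the cause of the change.

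Of the 10 splits of the 6 libraries into 3 and 3, 1 split, the one by genotype, gave 3770 called genes, and the highest count of the other splits was 0 by edgeR (57 to 947 genes at an unadjusted p under 0.05). For the list test 2 splits gave as many as 13 called lists, the highest of the others being 13 (control replicates 1 and 3 with knockout replicate 1 against the rest). The other splits mix the genotypes, so the difference between genotypes adds to the spread within their groups. Few called genes in them were therefore likely from the start. With 10 splits the share cannot be under 0.05.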
